A study of Homo sapiens with 24 samples.

How the data were processed

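Total RNA of human cell clones was measured on Illumina expression arrays. Per the labels, RNA was extracted with QIAGEN RNeasy columns and labelled with biotin with an Ambion MessageAmp kit. The 24 arrays covered 14 clones of 3 cell lines, each labelled wild type or knockout for Rap1, which is encoded by TERF2IP. A clone of HCT116 or HT1080 had 2 arrays and a clone of ARPE-19 had 1; the parental ARPE-19 culture was counted as 1 of the wild-type clones. The clone was the replicate, so the 2 arrays of a clone were averaged first. The labels do not say whether the 2 arrays of a clone came from separate cultures.

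The deposited values were on a log scale with both signs, and each probe had been centred on its median over the arrays of its own cell line. The largest such median in any line was 5e-07. The base of the log was not given in the sources used here, and the deposited values were taken as log2; with another base, every change would be multiplied by a constant and the tests would stay as they are. Background correction, normalization between arrays and the software were not given in the sources used here. Because of the centring, the table holds differences between arrays of a line and no levels, so a probe's signal over background is unknown, and the small numbers of clones and arrays limit the precision. All values below are therefore relative to the median of the line.

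The value table held 47323 probes. The probe annotation gave 1 gene symbol for 30113 of them, several for 8 and none for 17202, which were left unnamed. Symbols were updated through the Entrez identifier for 30074 probes with the RefSeq gene table of assembly GRCh38.p14, which was used only for names and gene order. This left 20046 genes, of which 6691 had more than 1 probe. In ARPE-19, 4 probes had missing values.

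The designs, gene lists, named-gene rule and alternatives were fixed before the data were examined, except where an item is called added after seeing the data. The planned filter on dim probes and the planned choice of the brightest probe of a gene needed levels, which centred values do not hold. They were replaced, after seeing the data, by no filter and by the probe with the largest variance over the HCT116 and HT1080 arrays. This rule does not use the genotype labels. As the values are centred per line, that variance includes any change between genotypes, so the rule favours probes with larger changes. Fits of HCT116 with HT1080 alone were also added after seeing the data, because probes of one gene did not move together in ARPE-19.

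Knockout was compared with wild type by limma (lmFit and eBayes, two-sided, Benjamini-Hochberg over all genes tested, threshold adjusted p 0.05), within each line and across lines with the line as a fixed factor. Genes whose change differed between lines were tested by the interaction of genotype with line. Changes are log2 knockout minus wild type and are given ± the standard error of the fit. TERF2IP was also tested by an exact permutation test of clone values. Genes were called parted where all knockout clones lay on the same side of all wild-type clones of the line. For counts of genes, the genotype labels were regrouped within lines, using all groupings or 100 drawn with a fixed seed.

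With each array centred on its median, the median value of each chromosome's genes in each clone was compared with that of random gene sets of the same size, in 322 tests adjusted together. This permutation test was run with 2000 gene shuffles and, after that result was seen, with 10000.

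Gene lists were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry, adjusted over 80 tests of 16 lists in 5 comparisons. The camera tests of lists between HCT116 and HT1080 were adjusted separately, over 16 lists. Camera compares a list with all other genes, so its direction is relative to the mean statistic of the genes outside the list. Of the list members, 6 of 6 were measured for shelterin, 29 of 32 for telomerase and telomere maintenance, 34 of 36 for NF-kB targets, 28 of 30 for p53 targets, 29 of 32 for DNA damage signalling and repair, 32 of 32 for proliferation, 32 of 33 for interferon-stimulated genes and 27 of 29 for fatty acid and glucose metabolism. The numbers were 20 of 21 for heat shock and unfolded protein stress, 20 of 21 for hypoxia and glycolysis, 23 of 24 for epithelial markers, 26 of 27 for mesenchymal and matrix markers, 16 of 17 for retinal pigment epithelium markers and 26 of 28 for cancer-testis genes. Subtelomeric genes were the 10 outermost protein-coding genes of each chromosome end (295 of 390 measured), and the neighbours of TERF2IP were the 5 protein-coding genes on each side (6 of 10 measured). The other members were not analysed here.

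The genes named were, per comparison, the shelterin genes and up to 10 higher and 10 lower genes past the threshold. Where fewer passed, each direction was filled up to 5 with the largest changes among parted genes. Up to 4 members of each list past the threshold, over all genes or over the list alone, and the 3 members of each list with the largest change were added, as were the 5 genes with the smallest p for a difference between lines. Genes of the Y chromosome and XIST were left out of the named genes. For each named gene with several probes, the change of every probe was computed.

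The alternatives were each array centred on its median, the mean of all probes of a gene, all probes one by one, all 6 groups in 1 fit, all arrays with the clone as a random block, the same with the array number as a replicate block, arrays as independent, first or second arrays alone, and each clone left out in turn. A robust prior, the 4 groups of HCT116 and HT1080 in 1 fit and the 50% of genes with the larger SD were added after seeing the data.

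The fits were tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale. At these sizes, 98% and 100% of the changed genes were recovered in HCT116, 92% and 98% in HT1080, 100% and 100% in ARPE-19 and 99% and 100% in HCT116 with HT1080, with 11, 24, 22 and 13 false calls. The simulated noise was independent between genes, and the changed genes were drawn at random. The recovered shares do not carry over to the measured changes. At least 2-fold changes were measured in 50 genes in HCT116 and 90 in HT1080, but only 3 and 2 genes were called. R 4.3.3 with limma 3.58.1 was used for the statistics, and Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 for the figures.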

Results

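Gene expression was compared between knockout and wild-type clones of Rap1 in 3 human cell lines. Rap1, encoded by TERF2IP, is a subunit of shelterin, the protein complex that coats telomeres. The clones had been made with TALENs, engineered nucleases that cut a chosen DNA sequence, and the study asked whether Rap1 is needed to protect telomeres and to set their length. HCT116 is a colorectal carcinoma line, HT1080 a fibrosarcoma line and ARPE-19 a line of retinal pigment epithelium. HCT116 had 3 wild-type clones (15, 20 and 23) and 3 knockout clones (10, 21 and 28), and HT1080 had 2 wild-type clones (2 and 9) and 2 knockout clones (8 and 21), all with 2 arrays each. ARPE-19 had wild-type clone 23 and the parental culture against knockout clones 25 and 30, with 1 array each. Values were log2 differences from the median of the line, so each line was compared only with itself.

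TERF2IP, the targeted gene, was measured by 1 probe and was taken first as a check of the labels. In HT1080 its values were 1.25 and 1.14 in wild-type clone 2 and 1.11 and 1.14 in clone 9, against -1.68 and -1.79 in knockout clone 8 and -1.11 and -1.20 in clone 21. The difference in HT1080 was -2.61 ± 0.21 (SE, n = 2 and 2 clones), and it passed the threshold adjusted over the list alone for the shelterin genes but not over all genes (limma, adjusted p = 0.229). In HCT116 the clones labelled wild type and knockout overlapped. Wild-type clone 23 stood at 1.45 and 1.21, clone 15 at 0.12 and 0.069 and clone 20 at -0.28 and -0.26, while knockout clone 10 stood at -0.0070 and -0.44, clone 21 at -0.77 and -0.29 and clone 28 at 0.048 and 0.0070. The difference in HCT116 was -0.63 ± 0.36 (SE, n = 3 and 3 clones; limma, adjusted p = 0.639), and it was -0.16 without wild-type clone 23. Exact two-sided permutation tests of the clone values gave p = 0.3 in HCT116, where 0.1 is the smallest possible, and p = 0.333 in HT1080, where no smaller value is possible. With labels permuted within HCT116 and HT1080 together, the exact p was 0.05, against a smallest possible value of 0.0167. The genotypes of the HCT116 clones are therefore given below as labelled. The sources used here do not place the probe against the part of the gene that was altered, and a frameshift need not lower the transcript.

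**Figure D1:**
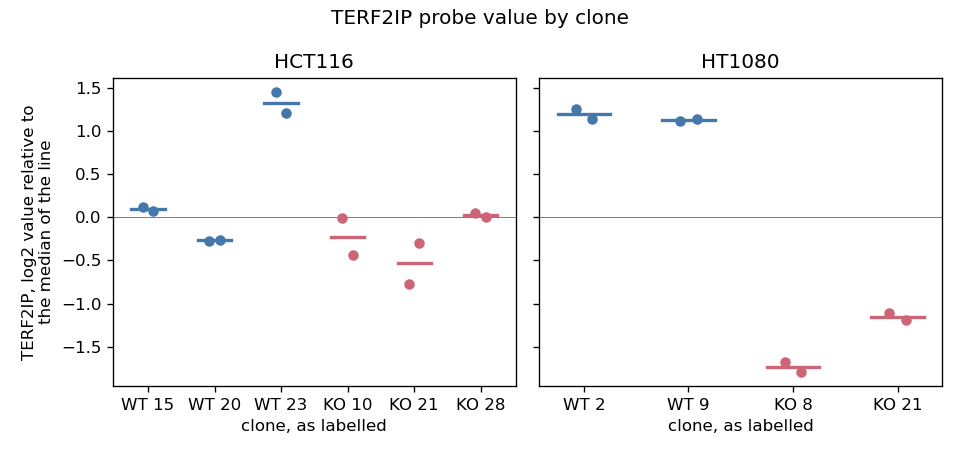
TERF2IP probe value (log2, relative to the median of the line) in each array (points) and the mean of each clone (lines) for the clones labelled wild type (WT, blue) and knockout (KO, red). The HT1080 knockout clones lie between -1.79 and -1.11 and the wild-type clones between 1.11 and 1.25, whereas in HCT116 only clone 23 stands apart, at 1.45 and 1.21.

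In HCT116, NR4A2, an orphan nuclear receptor, was the gene that rose past the threshold in the clones labelled knockout, by 1.05 ± 0.10. SUSD2, a membrane protein with a sushi domain, fell by 2.18 (-2.18 ± 0.21), and PPFIBP1, the adaptor protein liprin beta-1, fell by 1.30 (-1.30 ± 0.13). These 3 genes, 1 higher and 2 lower, were all that passed among 20046 genes (limma, adjusted p = 0.0435 for each, n = 3 and 3 clones), and 1641 genes had an unadjusted p under 0.05. Changes of at least 2-fold were measured in 50 genes, 22 higher and 28 lower.

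Among the genes of HCT116 that did not pass, the largest differences with no overlap between the clones were those of SLC2A3, the glucose transporter GLUT3 (-2.37 ± 0.29, adjusted p = 0.0807), and PKIB, an inhibitor of protein kinase A (1.81 ± 0.32, adjusted p = 0.314). TNNC1, which encodes a troponin C, differed by -1.80 ± 0.36 and the neurotrophin gene BDNF by -1.53 ± 0.26. ACSL5, an acyl-CoA synthetase, differed by 1.72 ± 0.48, the hyaluronan synthase HAS3 by 1.58 ± 0.42 and the transcription factor KLF4 by 1.25 ± 0.28. Probes of a gene did not always give the same change. The other probes of PPFIBP1 gave -0.94, -0.26 and -0.0060, and the other probe of PKIB gave 0.077, whereas NR4A2 gave 0.86 with its other probe. In all, 14 of the 17 other probes of the 10 genes named here had the same sign, and 4 reached at least 50% of the change; the 3 of opposite sign were probes of BDNF (0.11, 0.029 and 0.014). All genes together were shifted by a median of 0.048, and clones labelled knockout and wild type did not overlap for 15.3% of genes (2360 higher and 717 lower), where chance gives 10%. By direction 11.8% were higher and 3.58% lower, where chance gives 5% each way. The excess thus lay on the higher side alone, the side of the shift of all genes.

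The 3 calls in HCT116 were lost with each array centred on its median (0 genes), with the mean of the probes of a gene (0 genes) and with a robust prior (0 genes). NR4A2 was lost most often, in 4 of 12 settings and on leaving out 5 of the 6 clones, against 3 settings and 4 clones for SUSD2 and for PPFIBP1. NR4A2 was lost with second arrays alone too (adjusted p = 0.0887, the highest of a range from 9.01e-06). PPFIBP1 reached a higher adjusted p over its settings, 0.425. The calls also depended on single clones, since 0 genes passed without wild-type clone 23 or knockout clone 28, 1 passed without wild-type clone 15, wild-type clone 20 or knockout clone 10, and 78 passed without knockout clone 21, with the same 3 among them.

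The shelterin genes were lower as a list in the HCT116 clones labelled knockout, with 0 higher and 6 lower (camera, adjusted p = 0.00364; adjusted p = 0.579 with an estimated correlation). Besides TERF2IP, POT1, which binds single-stranded telomeric DNA, differed by -0.25 ± 0.11, TINF2 by -0.19 ± 0.10, TERF2 by -0.10 ± 0.09, TERF1 by -0.10 ± 0.10 and ACD by -0.071 ± 0.10. The other probes gave 0.051 and -0.057 for POT1 and 0.095 and -0.071 for TERF1. Without TERF2IP the list's adjusted p was 0.0139, and without knockout clone 21 it was 0.063. The proliferation genes were also lower as a list, with 10 higher and 22 lower (camera, adjusted p = 3.17e-04; adjusted p = 0.973 with an estimated correlation), led by the kinetochore gene CENPF (-0.35 ± 0.13), the spindle checkpoint kinase TTK (-0.31 ± 0.09) and the motor protein KIF11 (-0.27 ± 0.12). That call was lost without wild-type clone 15 (adjusted p = 0.172) or knockout clone 10 (adjusted p = 0.0959), whose list means of 0.168 and -0.140 were the highest and lowest of the 6 clones.

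The other lists did not pass camera in HCT116, with any correlation. Of the p53 targets 20 were higher and 8 lower (adjusted p = 0.0988), with GDF15 at 0.89 ± 0.45, the cell cycle inhibitor CDKN1A at 0.81 ± 0.25 and SPATA18 at 0.49 ± 0.20. Of the NF-kB targets 26 were higher and 8 lower (adjusted p = 0.888), with PLAU at -0.32, TNFAIP3 at 0.27 and RELB at 0.26. The counts higher and lower were 15 and 14 for telomerase and telomere maintenance (adjusted p = 0.399; STN1 0.51, FEN1 -0.32), 9 and 20 for DNA damage signalling and repair (adjusted p = 0.101; TOPBP1 -0.30, MDC1 -0.26) and 18 and 14 for interferon-stimulated genes (adjusted p = 0.860; IFIT1 -0.47, IFIT2 -0.46). They were 21 and 6 for fatty acid and glucose metabolism (adjusted p = 0.271; PPARG 1.01, PCK2 0.54), 14 and 6 for heat shock and unfolded protein stress (adjusted p = 0.879; DDIT3 1.00, TRIB3 0.85) and 10 and 10 for hypoxia and glycolysis (adjusted p = 0.888; NDRG1 1.23, ADM -0.57). Among the cell type markers, the epithelial list had 20 higher and 3 lower (adjusted p = 0.157; MAL2 0.88, RAB25 0.50), the retinal pigment epithelium list 13 and 3 (adjusted p = 0.399; KRT7 -1.01, LRAT 0.42) and the mesenchymal and matrix list 15 and 11 (adjusted p = 0.157). The mesenchymal and matrix list passed fry's test for changes in either direction (mixed adjusted p = 0.0104) although none of its members passed, and it also passed that test in ARPE-19 (mixed adjusted p = 0.00545), where probes of one gene did not move together. The largest changes in HCT116 were S100A4 at -1.30 ± 0.59, TWIST1 at -0.82 ± 0.28 and vimentin (VIM) at -0.75 ± 0.54. The cancer-testis genes, whose paralogs share probe sequence, had 21 higher and 5 lower (adjusted p = 0.157; MAGEA10 0.25, PRAME -0.23). Of the subtelomeric genes 193 were higher and 102 lower (adjusted p = 0.957; FOXQ1 -0.79, CRIP1 -0.76), and of the neighbours of TERF2IP 4 were higher and 2 lower (adjusted p = 0.926; GABARAPL2 0.15, ADAT1 -0.14). Another probe had the opposite sign for IFIT1 (0.091), PPARG (-0.074) and PRAME (0.042). No member of any list passed the threshold in HCT116, adjusted over all genes or adjusted over the list alone.

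In HT1080, CDCP1, a transmembrane glycoprotein phosphorylated by Src kinases, rose by 3.65 ± 0.15 in the knockout clones, and PTGR1, a prostaglandin reductase, rose by 2.07 ± 0.09. These 2 genes were the only calls among 20046 genes (limma, adjusted p = 0.0414 for each, n = 2 and 2 clones), and 1004 genes had an unadjusted p under 0.05. The other probes of CDCP1 gave 2.64, 2.09 and 1.30, and that of PTGR1 gave 1.81. Changes of at least 2-fold were measured in 90 genes, 40 higher and 50 lower.

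The largest differences in HT1080 that did not pass and had no overlap between the clones were higher values of ATP9A, a phospholipid-transporting ATPase (3.45 ± 0.27, adjusted p = 0.229), the secreted glycoprotein gene NELL2 (2.56 ± 0.25) and TRIML2 (2.41 ± 0.58). Lower values were measured for EEF1A2, a translation elongation factor (-3.00 ± 0.75), FCMR, the Fc receptor of IgM (-2.79 ± 0.47), TERF2IP, the thymosin gene TMSB15B (-2.50 ± 0.22) and IAH1 (-2.48 ± 0.86). The other probes of ATP9A gave 0.044 and -0.11, and those of TMSB15B gave -1.10, -1.02 and -0.034. The clones of the genotypes did not overlap for 36.7% of genes (2848 higher and 4514 lower), where chance gives 33.3%. By direction 14.2% were higher and 22.5% lower, where chance gives 16.7% each way, and all genes together were shifted by a median of -0.026. Both calls were lost with the mean of the probes of a gene (0 genes), and 0 genes passed without knockout clone 8 or knockout clone 21, 4 without wild-type clone 2 and 8 without wild-type clone 9.

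The NF-kB targets, genes of inflammatory signalling, were lower as a list in the HT1080 knockout clones, with 5 higher and 29 lower (camera, adjusted p = 8.30e-06; adjusted p = 0.666 with an estimated correlation). For 16 of the 34, or 47.1%, both knockout clones lay below both wild-type clones, where chance gives 16.7% and 22.5% of all genes did so. The chemokine CXCL8 fell by 1.14 (-1.14 ± 0.20) and the gelatinase MMP9 by 0.80 (-0.80 ± 0.13), the 2 members that passed adjusted over the list alone, and 0 passed adjusted over all genes. IL1B stood at -2.09 ± 1.02, PTGS2 at -1.42 ± 0.36 and IL6 at -1.37 ± 0.34 without passing. The mean of the list was 0.340 in wild-type clone 2 and 0.116 in clone 9, against -0.108 in knockout clone 8 and -0.246 in clone 21. The list kept its call on leaving out each clone in turn, with adjusted p between 8.16e-07 and 0.00349.

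The proliferation genes were higher as a list in HT1080, with 30 higher and 2 lower (camera, adjusted p = 1.06e-08; adjusted p = 0.973 with an estimated correlation). The cyclin gene CCNE1 stood at 0.61 ± 0.10, the replication factor CDC45 at 0.46 ± 0.17 and MCM3 at 0.46 ± 0.50, but the other probe of CCNE1 gave -0.10. DNA damage signalling and repair was higher as well, with 22 higher and 7 lower (camera, adjusted p = 0.00613; adjusted p = 0.973 with an estimated correlation), with FANCI at 0.43 ± 0.09, BRCA1 at 0.39 ± 0.18 and RIF1 at 0.34 ± 0.14 (0.024 with its other probe). Both calls rested on wild-type clone 2: without it the adjusted p was 0.281 for proliferation and 0.536 for DNA damage signalling and repair. The mean of the proliferation list was -0.317 in that clone, against 0.0185 in wild-type clone 9, 0.0479 in knockout clone 8 and 0.0868 in knockout clone 21. Both knockout clones lay above both wild-type clones for 53.1% of the proliferation genes, where 14.2% of all genes did so. For DNA damage signalling and repair the share was 17.2%, near that of all genes.

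The remaining lists did not pass camera in HT1080. The counts higher and lower were 2 and 4 for shelterin (adjusted p = 0.157; TERF1 -0.35, TINF2 -0.12, TERF2 -0.042, ACD 0.12, POT1 0.10), 17 and 12 for telomerase and telomere maintenance (adjusted p = 0.271; PINX1 0.42, SMG5 0.37, STN1 -0.36) and 4 and 24 for p53 targets (adjusted p = 0.131; SPATA18 -1.04 ± 0.65). They were 14 and 18 for interferon-stimulated genes (adjusted p = 0.919; MX1 1.35 ± 0.36, IFI27 1.14 ± 1.33), 11 and 16 for fatty acid and glucose metabolism (adjusted p = 0.965; PPARGC1A -0.50, PCK2 0.45), 10 and 10 for heat shock and unfolded protein stress (adjusted p = 0.283; DDIT4 -1.25 ± 0.86, HSPA1B 0.73) and 6 and 14 for hypoxia and glycolysis (adjusted p = 0.888; NDRG1 -0.67). Of the epithelial markers 6 were higher and 17 lower (adjusted p = 0.399; CLDN4 -0.33), of the mesenchymal and matrix markers 10 and 16 (adjusted p = 0.888; LOX -1.40 ± 0.46, MMP3 -1.30 ± 1.81) and of the retinal pigment epithelium markers 4 and 12 (adjusted p = 0.511; MITF 0.33). The cancer-testis genes had 12 higher and 14 lower (adjusted p = 0.919; PAGE1 -1.02 ± 0.75, GAGE7 0.56), the subtelomeric genes 139 and 156 (adjusted p = 0.774; TRIML2 as above, GLB1L2 0.94, CRIP2 -0.83) and the neighbours of TERF2IP 2 and 4 (adjusted p = 0.888; CNTNAP4 -0.23). Other probes gave -0.090 and -0.076 for POT1, -0.22 and 0.0065 for MITF and 0.29 and -0.021 for PCK2. Median, mean and set test differed in sign for 5 lists in HCT116 and 3 in HT1080, none of which passed camera.

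**Figure D2:**
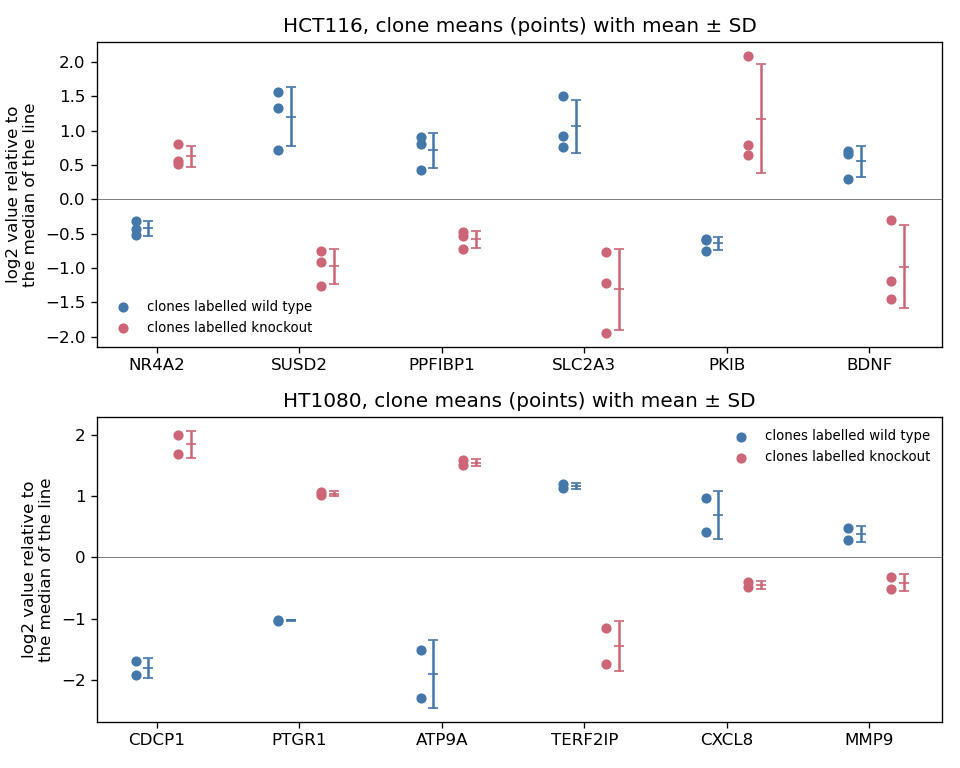
Clone means (points, log2 relative to the median of the line) and mean ± SD (bars beside them) of 6 genes in HCT116 and 6 in HT1080 for clones labelled wild type (blue) and knockout (red). NR4A2, SUSD2 and PPFIBP1 passed the threshold in HCT116 and CDCP1 and PTGR1 in HT1080. The clone groups are apart for all 12 genes drawn, which were chosen for passing a threshold or for clones that do not overlap.

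The 2 lines were then set against each other. The change of 10 genes differed between HCT116 and HT1080 (limma interaction, adjusted p under the threshold; 1795 genes with an unadjusted p under 0.05), with 5 changes higher in HCT116 and 5 in HT1080. ACOT1, an acyl-CoA thioesterase, stood at 0.28 in HCT116 and at -1.31 in HT1080, a difference of 1.59 ± 0.12 (adjusted p = 0.00176). Its near-identical neighbour ACOT2 was also among the 10 (0.11 and -1.28), and their probes cannot be assumed to be specific. CDCP1 differed by -3.23 ± 0.25 (0.42 in HCT116 and 3.65 in HT1080), ATP9A by -3.56 ± 0.31 (-0.11 and 3.45), TMSB15B by 2.47 ± 0.22 (-0.031 and -2.50) and NR4A2 by 1.95 ± 0.18 (1.05 and -0.90). The other members, named here because they complete the count, were NELL2, PTGR1, RAPGEF5 and SIGLEC14. The difference of TERF2IP between the lines did not pass (adjusted p = 0.468). The count of 10 was 28 without HCT116 knockout clone 21, 47 without HT1080 wild-type clone 2, 71 without wild-type clone 9, 21 without knockout clone 8 and 33 without HT1080 knockout clone 21.

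Lists whose change differed between the lines were the NF-kB targets (lower in HT1080; camera, adjusted p = 1.74e-04; adjusted p = 0.402 with an estimated correlation) and the p53 targets (lower in HT1080; adjusted p = 0.032; adjusted p = 0.776 with an estimated correlation). Proliferation (adjusted p = 1.29e-11) and DNA damage signalling and repair (adjusted p = 0.00102) were higher in HT1080, with adjusted p = 0.541 for each with an estimated correlation. No clone was left out in turn for these tests between the lines. Within HT1080 the mean of the proliferation list was -0.317 in wild-type clone 2. It was 0.0185, 0.0479 and 0.0868 in wild-type clone 9 and knockout clones 8 and 21. For DNA damage signalling and repair the means were -0.162 in wild-type clone 2 and 0.00253, 0.0279 and 0.0273 in those clones. Whether these differences between the lines rest on wild-type clone 2 was not tested. Of 34 NF-kB targets, 24 (70.6%) were higher in HCT116 and lower in HT1080, as were 17 of 28 p53 targets (60.7%), where 40.0% of all genes were. The reverse held for 22 of 32 proliferation genes (68.8%) and 17 of 29 genes of DNA damage signalling and repair (58.6%), where it held for 17.6% of all genes. Across all 20046 genes, which are not independent replicates, the changes in the 2 lines had r = -0.0586 and Spearman's rho = -0.113, and 12 of 60 groupings of the clones gave an r as far from 0.

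**Figure D3:**
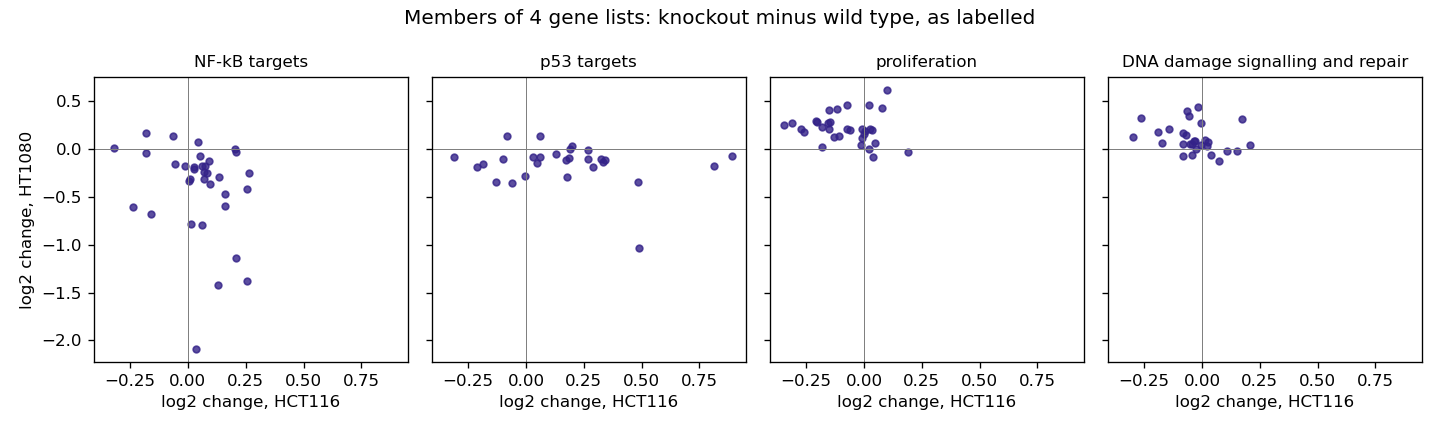
Change of each measured member (points) of 4 gene lists in HCT116 (horizontal axis, log2) and HT1080 (vertical axis, log2), knockout minus wild type as labelled. Of 34 NF-kB targets 29 lie below 0 in HT1080 and 26 above 0 in HCT116. Of 32 proliferation genes 30 lie above 0 in HT1080 and 22 below 0 in HCT116. All genes together were shifted by a median of 0.048 in HCT116 and -0.026 in HT1080.

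Fitted together, HCT116 and HT1080 gave 0 genes past the threshold (limma, n = 5 and 5 clones; 944 genes with an unadjusted p under 0.05). The largest changes shared in direction by parted clones of the lines were HAS3 (1.35 ± 0.30), ACSL5 (1.20 ± 0.38), the kinase SGK1 (0.72 ± 0.30), the phosphatase subunit PPP2R2B (0.66 ± 0.29, with another probe at -0.016) and the scaffold protein AKAP12 (0.66 ± 0.12) on the higher side. On the lower side were SLC2A3 (-1.57 ± 0.36), the retinoic acid binding protein CRABP2 (-1.21 ± 0.21), TNNC1 (-1.14 ± 0.34), PPFIBP1 (-0.99 ± 0.15) and STING1, the adaptor of cytosolic DNA sensing (-0.83 ± 0.15). Clones were parted the same way in HCT116 and HT1080 for 323 genes (211 higher and 112 lower), or 1.61% where chance gives 1.67%. Without HT1080 wild-type clone 2 or wild-type clone 9, 1 gene passed.

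Shelterin was lower as a list over the 2 lines, with 1 higher and 5 lower (camera, adjusted p = 9.55e-04; adjusted p = 0.170 with an estimated correlation; adjusted p = 0.0183 without TERF2IP, by camera). TERF2IP passed adjusted over the list alone (-1.42 ± 0.39). NF-kB targets were lower, with 6 higher and 28 lower (camera, adjusted p = 0.0012; adjusted p = 0.973 with an estimated correlation); IL1B stood at -0.81 ± 0.53 and PTGS2 at -0.49 ± 0.28. The lines did not share this direction: in HT1080 5 were higher and 29 lower, but in HCT116 alone 26 were higher and 8 lower. In HCT116 the list did not pass against the other genes (camera, adjusted p = 0.888), and all genes together were shifted by a median of 0.048. The count there is therefore not read as an opposite change of the list. The NF-kB call was lost without HT1080 wild-type clone 2 (adjusted p = 0.214) or HT1080 knockout clone 21 (adjusted p = 0.0786). The other 14 lists did not pass, with adjusted p from 0.103 for the mesenchymal and matrix markers to 0.957 for the interferon-stimulated genes.

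In ARPE-19, 60 entries of the gene table passed the threshold, 31 higher and 29 lower (limma, n = 2 and 2; 1145 with an unadjusted p under 0.05), but they are not read here as named genes. Probes with the same gene name did not move together in this line. The median correlation over the arrays was 0.0574 for 211 pairs of such probes, close to the 0.0455 of random pairs, against 0.777 for 229 pairs in HCT116 and 0.897 for 250 pairs in HT1080. The values under the name of the TERF2IP probe were 0.013 in wild-type clone 23 and -0.013 in the parental culture, against 0.16 and -0.12 in knockout clones 25 and 30. No gene of ARPE-19 is named for this reason, and its lists, of which 0 of 16 passed camera and 1 (mesenchymal and matrix markers) passed fry's mixed test, are not read as results on those genes. The count was 29 without knockout clone 25.

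**Figure D4:**
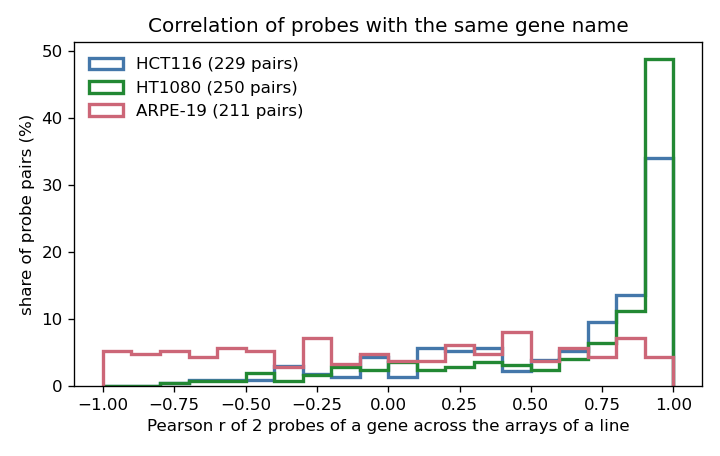
Share of probe pairs (%) by the Pearson correlation of 2 probes with the same gene name across the arrays of a line. The pairs gather near 1 in HCT116 (median 0.777) and HT1080 (median 0.897) and spread over the whole range in ARPE-19 (median 0.0574).

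The planned fits over all 3 lines include the ARPE-19 values under these names and share this limit. With 7 and 7 clones, 0 genes passed (limma; 985 with an unadjusted p under 0.05), the change of 54 differed between the lines (1681 with an unadjusted p under 0.05), and 49 were parted the same way in all lines (33 higher and 16 lower), or 0.244% where chance gives 0.278%. Shelterin (camera, adjusted p = 9.55e-04; adjusted p = 0.168 with an estimated correlation) and NF-kB targets (camera, adjusted p = 0.0012; adjusted p = 0.973 with an estimated correlation) were lower as lists, the second no longer without HT1080 wild-type clone 2 (adjusted p = 0.109). In HCT116 alone, 26 of the 34 NF-kB targets were higher, but the list did not pass there (camera, adjusted p = 0.888) and all genes were shifted by a median of 0.048. The count of 54 was 34 without HCT116 wild-type clone 20, 35 without HCT116 wild-type clone 23, 113 without HT1080 wild-type clone 2, 140 without HT1080 wild-type clone 9 and 84 without HT1080 knockout clone 21.

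Clones of a genotype differed from each other by more than arrays of a clone did. The SD was 0.134 between the arrays of a clone and 0.171 between clone means of a genotype in HCT116, and 0.131 and 0.212 in HT1080. The clone means average 2 arrays each, so these SDs are on unlike scales. On the scale of single arrays, the root of the mean square between clones was 1.81 times that between arrays in HCT116 and 2.29 times in HT1080. The mean square between clones still includes the spread between arrays, so these ratios overstate the SD between clones alone. Tested against the spread between the arrays of a clone, clones of the same genotype differed for 4272 genes (21.3%) in HCT116 and 3411 genes (17.0%) in HT1080, but as those arrays may share a culture, differences between cultures are not set apart from differences between clones. Over genes, arrays of a clone had a median correlation of 0.517 in HCT116 and 0.626 in HT1080, against -0.0594 and -0.187 for other clones of the same genotype and -0.142 and -0.175 for clones of the other genotype. The low values are partly set by the centring on the line's median.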

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

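The tests chosen only after the results were seen were all fits of HCT116 with HT1080 alone, the tests of lists between the 2 lines, the groupings of parted genes, the register, noise and shift tests of ARPE-19, 3 of the 4 tests of TERF2IP in HCT116 (array noise, exchanged clones and a transcript left in place), and the tests of chance and of a single array on chromosome 13.

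Genes whose change differed between the lines drew attention because the difference itself was tested by an interaction term. With HCT116 and HT1080 the count was 10, and the 5 genes with the smallest p, as the change in HCT116 minus that in HT1080, were ACOT1 (1.59), CDCP1 (-3.23), ATP9A (-3.56), TMSB15B (2.47) and NR4A2 (1.95). The value of ATP9A rests on 1 of its 3 probes. The count was 28 without HCT116 knockout clone 21, and 47, 71, 21 and 33 without HT1080 wild-type clone 2, wild-type clone 9, knockout clone 8 and knockout clone 21. Of the 60 groupings of the clones within the lines, 10 gave as many genes, the highest of the others 14, so chance is not excluded as the source of the count. With all 3 lines the count was 54, and it was 34 and 35 without HCT116 wild-type clones 20 and 23, 113 and 140 without HT1080 wild-type clones 2 and 9, and 84 without HT1080 knockout clone 21. Of 100 groupings drawn from 360, 6 gave as many, with 64 as the highest of the others, so chance is not excluded there either.

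Gene lists drew attention for the same reason, a tested difference between HCT116 and HT1080. Adjusted over the 16 lists of this comparison alone, the p from camera was 1.74e-04 for NF-kB targets and 0.0320 for p53 targets. It was 0.00102 for DNA damage signalling and repair and 1.29e-11 for proliferation. With an estimated correlation between the genes of a list, the values were 0.402, 0.776, 0.541 and 0.541, so none of the 4 differences passed. No clone was left out in turn for these differences. As given above, the calls of proliferation and of DNA damage signalling and repair within HT1080 rested on wild-type clone 2. The proliferation call within HCT116 was lost without wild-type clone 15 or knockout clone 10. The tests therefore do not show whether the differences between the lines hold without single clones. No explanation was tested for these 4 lists.

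A signal in data that the comparisons of genes do not use was the third reason. When all 47323 probes were tested one by one, 15 passed the threshold in HCT116, and 4 of them carried no single gene name. In HT1080, 2 probes passed and 0 of them lacked a name (limma). Array medians, array SDs and TERF2IP were also searched in each group of 4 or more arrays for a value far from the others. None of these 12 searches found one, where chance finds about 1 in 20, but since the 2 arrays of a clone lie close together, a search over arrays can hardly find a deviating clone.

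The remaining counts were compared with other groupings of the clones as well. In HCT116, 1 of the 10 groupings, the real one, called 3 genes, and the highest of the others called 0, but 10 groupings are too few for a share under 0.05. HT1080 and ARPE-19 have 3 groupings each, which is also too few. There the real one called 2 genes and 60 entries, and the highest of the others called 0. With 0 genes called in all lines and 0 in HCT116 with HT1080 (limma; 985 and 944 genes with an unadjusted p under 0.05), all 100 drawn groupings and all 60 groupings gave as many, the highest of the others being 0 and 1. For genes parted the same way in all lines, 49 of 100 groupings gave at least the real count of 49, the highest of the others 155, against a chance share of 0.278% of genes and 0.244% observed. For HCT116 with HT1080, 26 of 60 groupings gave at least the real 323, the highest of the others 794, against a chance share of 1.67% and 1.61% observed. Chance is not excluded for these counts, and groupings that part many more genes than the labelled one point to some structure of the samples, whose nature was not tested.

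In ARPE-19, probes with the same gene name did not move together. Too few arrays are argued against, since the first array of each of the 4 HT1080 clones alone gave a median correlation of 0.942, and so is a displacement by a fixed number of places, since no shift raised the rank correlation of the probes' SD with the other lines above 0.0183, where HCT116 with HT1080 had 0.172. Noise of the ARPE-19 arrays stays open: 50 probes lay clearly apart between wild type and knockout, against at most 4 in another pairing of the arrays, but although the other probes of 18 of them followed by a median share of only -0.000872 of the change, those of 10 such probes in HT1080 followed by 0.468, short of the bound set for excluding noise. Values out of register with the probe names remain a candidate explanation, since the correlation of 0.0574 lay near the 0.0455 of random pairs. The same correlation raised the question, so a loss of register is not established, and no biological explanation was tested.

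TERF2IP overlapped between the HCT116 clones labelled wild type and knockout, with wild-type clone 23 alone standing apart. Array noise is argued against for the high value of clone 23. Its gap to the next clone was 2.61 times the largest difference between the 2 arrays of a clone. For the overlap of the remaining clones array noise stays open, since the 2 arrays of a clone differed by up to 0.47. Only if knockout lowers the transcript is an exchange with a knockout clone argued against, since the highest knockout clone lay 1.30 below clone 23. That gap is part of the observation that raised the question, so it is no separate test. Wrong labels on wild-type clones 15 and 20 cannot be told apart from right ones: 0 knockout clones correlated better over genes with clone 23 than with both others, but knockout clone 10 had r = -0.200 with clone 23 and -0.313 with clone 15. Mutations that leave the transcript in place may also give this pattern, in which case an exchange stays open too, and the 1 probe of the gene cannot tell these apart from wrong labels. The knockout itself, the biological difference of the design, was not tested at the level of protein.

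In HT1080 knockout clone 21, the 346 genes of chromosome 13 were shifted by a median of -0.070, against -0.0082 and 0.024 in wild-type clones 2 and 9 and 0.024 in knockout clone 8, and 46.5% of them were lowest in this clone, against 24.0% of genes elsewhere. A chance draw of genes is argued against by a permutation test with an adjusted p of 0.0161 over 322 tests of chromosomes and clones (p = 0.0001, the smallest that 10000 gene shuffles can give), although a first run of 2000 shuffles could reach only 0.0536 and the number was raised after that was seen. The shuffles treat genes as independent; 6 of the 322 tests passed, the other 5 with shifts between -0.029 and 0.024. A deviating array is argued against, since the smaller shift of the 2 arrays was -0.061 and the other -0.082. Cut into 4 equal parts in order along the chromosome, its genes shifted by -0.033, -0.18, -0.10 and -0.018. Fewer copies of the whole chromosome stay possible, since all 4 parts shifted down. The parts were not tested singly, and -0.018 lies within the range of the other 5 shifts. A loss of the middle part alone therefore stays open too.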

How the results depend on the processing

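The alternatives chosen only after seeing the data were the robust prior without a trend, the 4 groups of HCT116 and HT1080 in 1 fit, the 50% of genes with the larger SD, shelterin without TERF2IP, and everything that fits HCT116 with HT1080 alone. Not run were the stricter filter on dim probes, quantile normalization, other pseudocounts, a prior with a trend and other probes of TERF2IP, which has 1. No filter became the main setting. For lists, the robust prior and both block fits were not run. Over 12 settings, 668 of 726 values of 61 named genes in HCT116 kept their direction and their side of the threshold, 46 passed it, 10 no longer did and 2 changed sign without being called; in HT1080 these were 659, 64, 2 and 2 of 727 values. Over 10 settings of HCT116 with HT1080 they were 574, 27, 0 and 4 of 605. The cause of the changes below was not tested except where the construction shows it.

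With each array centred on its median, 0 genes passed in HCT116, where 3 had, and with a robust prior 0 did as well. The mean of the probes of a gene gave 0 genes in HCT116, 0 in HT1080, where 2 had, and 27 in ARPE-19, where 60 had. All probes one by one, with more tests, gave 15 probes in HCT116, 139 in ARPE-19 and 136 for the difference between 3 lines, where 54 genes had passed. The 50% of genes with the larger SD, with fewer tests, gave 9 in HCT116 and 185 in ARPE-19, and the shelterin list in HCT116 then had an adjusted p of 0.0501, the highest over its settings, whose lowest was 0.00234. With all 6 groups in 1 fit, 14 genes passed in HCT116 and 46 in HT1080, and with 4 groups 7 and 21. First arrays alone gave 13 and 6, and second arrays 6 in HCT116. TERF2IP in HT1080 passed with first arrays (-2.58, adjusted p = 0.0401) and with all 6 groups (-2.61, adjusted p = 0.0108), within a range over its settings of 5.44e-06 to 0.391. The fit of all 6 groups estimates the spread in part from ARPE-19, where probes of one gene did not move together. Its counts and its TERF2IP result share that limit.

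Keeping all arrays makes the arrays of a clone count in part or in full as replicates. With the clone as a random block, 162 genes passed in HCT116, 68 in HT1080, 14 in all lines and 39 in HCT116 with HT1080, where 0 had passed in both of the joint fits, and the difference between 3 lines gave 239 and that between HCT116 and HT1080 162. With arrays as independent the counts were 301, 132, 60, 125, 483 and 443. With the array number added as a replicate block they were 120, 47, 13, 32, 215 and 130. The numbers do not pair arrays of different clones: after removing each clone's mean, the correlation between clones of the array 1 minus array 2 differences lay between -0.183 and 0.186 over 15 pairs in HCT116 and between -0.0620 and 0.154 over 6 pairs in HT1080.

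The adjusted p ranged over the 12 settings from 9.01e-06 to 0.0887 for NR4A2, from 1.31e-07 to 0.0721 for SUSD2, from 3.86e-06 to 0.425 for PPFIBP1, from 2.32e-08 to 0.398 for CDCP1 and from 1.66e-07 to 0.0999 for PTGR1. Gene lists by camera with an estimated correlation and by fry's test of a shared direction gave 0 past the threshold in HCT116, where 2 had passed with the preset correlation, 0 in HT1080, where 3 had, and 0 in all lines and 0 in HCT116 with HT1080, where 2 had in each (unadjusted p under 0.05 by camera for 7, 5, 3 and 3 lists). Subtelomeric genes did not pass with 5 or 20 genes at each end in any comparison. Among uncalled values, signs changed for ACD in HCT116 (0.028) and GABARAPL2 in HT1080 (0.0058) with first arrays, TMEM231 in HCT116 (-0.053) with second arrays and POT1 in HT1080 (-0.020) with the mean of probes. In HCT116 with HT1080 they changed for ACD with centred arrays (-0.0092) and for ACD (-0.059), TMEM231 (-0.050) and GABARAPL2 (-0.016) with second arrays.

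Leaving out each clone in turn leaves 1 clone in an arm in HT1080 and ARPE-19, and that clone is assumed to vary like those of the other group. The count ranged from 0 (without wild-type clone 23 or knockout clone 28) to 78 (without knockout clone 21) in HCT116, from 0 (without either knockout clone) to 8 (without wild-type clone 9) in HT1080, from 29 (without knockout clone 25) to 74 (without the parental culture) in ARPE-19 and from 0 to 1 (without HT1080 wild-type clone 2 or 9) in HCT116 with HT1080. It stayed at 0 in all lines. Differences between 3 lines ranged from 34 (without HCT116 wild-type clone 20) to 140 (without HT1080 wild-type clone 9), and those between HCT116 and HT1080 from 8 (without HCT116 wild-type clone 23) to 71 (without HT1080 wild-type clone 9). Lists past the threshold ranged from 1 (without knockout clone 10) to 5 (without knockout clone 28) in HCT116, with 4 without wild-type clone 20, from 2 (without wild-type clone 2) to 5 (without wild-type clone 9) in HT1080 and from 1 (without HT1080 wild-type clone 2) to 3 (without HT1080 knockout clone 21) in all lines. Genes parted the same way rose from 49 to between 83 and 148 in all lines and from 323 to between 541 and 845 in HCT116 with HT1080, whichever clone was left out, because fewer clones are parted more easily.

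Uncalled genes that changed sign on leaving out 1 clone, with their lowest and highest values, were ACD in HCT116 (-0.13 to 0.0092) and 15 genes in HT1080: TERF2 (-0.15 to 0.068), ACD (-0.063 to 0.31), POT1 (-0.059 to 0.27), TP53INP1 (-0.87 to 0.15), MCM3 (-0.30 to 1.22), IFI27 (-0.86 to 3.14), IFIT2 (-1.54 to 0.11), DDIT4 (-2.57 to 0.078), HSPB1 (-0.018 to 1.24), ALDOC (-0.71 to 1.75), MMP3 (-3.87 to 1.28), COL1A2 (-0.079 to 1.80), PAGE1 (-2.17 to 0.12), PRAME (-0.88 to 0.013) and KARS1 (-0.18 to 0.30). In HCT116 with HT1080 they were ACD (-0.068 to 0.061), STN1 (-0.012 to 0.29), IFI27 (-0.21 to 1.02), PAGE1 (-0.69 to 0.017) and GABARAPL2 (-0.017 to 0.14). Signal over background, which would limit these values, is unknown because the values are centred.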

Other observations

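The comparison of list medians over the groupings of the clones was a test chosen only after the results were seen, and no explanation was tested. The medians of the gene lists under the real labels were set beside those of the other groupings of the clones of each line, of which HCT116 has 10 and HT1080 has 3 with the real one included, too few for a share under 0.05. In HT1080 the median change of the NF-kB targets was -0.255, where the largest median of the other groupings was 0.112 in size. That of proliferation was 0.203 against 0.169, that of epithelial markers -0.0865 against 0.0194 and that of mesenchymal and matrix markers -0.0420 against 0.0230. In HCT116 the real grouping gave the largest median for shelterin (-0.145 against 0.132), for fatty acid and glucose metabolism (0.138 against 0.107) and for cancer-testis genes (0.125 against 0.113). For proliferation in HCT116, 5 of the 10 groupings gave a median at least as far from 0 as the real -0.0739. Each of the other lists had another grouping with a median at least as large.

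Among the 10 genes whose change differed between HCT116 and HT1080, the following were chosen after their values were seen. NELL2 changed by 0.0027 in HCT116 and 2.56 in HT1080, PTGR1 by -0.040 and 2.07, RAPGEF5 by 0.12 and 1.46, ACOT2 by 0.11 and -1.28 and SIGLEC14 by -0.0073 and -0.99. Each of them thus had a change in HCT116 of at most 0.12 in size. In HCT116, the 78 genes that passed without knockout clone 21 were 57 higher and 21 lower in the clones labelled knockout.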
